A study of Drosophila melanogaster
Mus musculus with 36 samples.

How the data were processed

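Small RNA libraries were made from mixtures of RNA of 2 species. Per the labels, total RNA of Drosophila melanogaster S2-S cells, which lack the endogenous Hen1 methyltransferase and express Arabidopsis thaliana HEN1, was mixed with total RNA of mouse embryonic stem (ES) cells, clone AN3-12, at 6 ratios of fly to mouse RNA from 1:1 to 1:100000. HEN1 places a methyl group on the 2'-hydroxyl of the last nucleotide of small RNAs, and sodium periodate oxidises 3' ends that lack it, so that these ends are lost to adapter ligation. Each mixture was divided into a part treated with periodate (oxidised) and an untreated part. RNAs of 18 to 30 nt were selected, 2S rRNA was depleted, and adapters with 4 random nucleotides at their ends were ligated.

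The 36 libraries fell into 12 groups of treatment by mixing ratio with 3 libraries each. The design text of the series speaks of 2 replicates of 12 libraries, and 3 sets of 12 were deposited. The set whose labels carry no replicate number was taken as replicate 1. Its mixtures held 25 µg of mouse RNA and were sequenced on a HiSeq2500, while replicates 2 and 3 used 50 µg of total RNA per mixture, or 25 µg per library, on a HiSeq2000. The replicate set therefore served as the batch given by the labels, and values are also given within each set. Whether the replicates came from separate cultures is not stated, and they may share cells. The labels state that each mixture was split, so oxidised and untreated libraries with the same number and ratio were taken as pairs. This pairing was checked on the deviations of the 300 most abundant entries from their group means. The median r over the 18 pairs was 0.243, 12 pairs had r above 0.1, and in 11 of 18 the library with the same number correlated best. In replicate 1 this held at every ratio, which the batch of that set would also give. In replicates 2 and 3 it failed at 1:10000, 1:100000 and other ratios, so the check does not establish the pairing. Both unpaired and blocked values are given.

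The deposited files hold expected counts, that is estimated read counts that can be fractional, 1 value per arm of a miRNA hairpin, for fly and mouse entries together, without scaling to depth. The unit was read from the file headers and tested on the values: between 80.6% and 98.1% of the values in a library were whole numbers (tolerance 0). The submitters' processing notes name cutadapt 1.2.1, HTSeq 0.6.1p1 and the builds mm10 and dm3, without stating their roles. The aligner and the rule by which reads matching several entries were shared are not given in the sources used here. Files of replicate 1 list 1781 entries and the others 2038. The 257 entries missing from replicate 1, none above 6 counts elsewhere, were set to 0. Of all entries, 372 were fly (dme) and 1666 mouse (mmu). No library was a copy of another: the smallest chi-square per degree of freedom over all 630 pairs of libraries was 2.91. No mature sequences were at hand, so identity between fly and mouse miRNAs could not be read from sequence, and no coordinates are given. Symbols of 210 of 214 fly hairpins were found in a gene table for the Drosophila Release 6 assembly, which is not the build the submitters used.

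Total counts per library are the miRNA counts in the file. Binomial intervals (Wilson, 95%) and floors of 3 counts cover counting error only, since amplified reads are not independent molecules.

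The log2 ratio of summed fly to summed mouse counts was computed in each library from the unrounded values, and the enrichment is the oxidised minus the untreated log2 ratio. Groups of 3 were compared by exact two-sided permutation tests, for which the smallest possible p is 0.1. The treatment over all ratios was tested with labels permuted within each ratio, and the trend of the enrichment by exact permutation of the ratios within replicate sets. Slopes of the log10 ratio on the log10 mixing ratio were fitted by least squares, with Pearson and Spearman coefficients from 100000 permutations (smallest possible p 1e-05). Detection was the expected number of fly miRNAs with 3 or more counts after every library was thinned to 3634 counts, the smallest library total after rounding of counts, by the hypergeometric distribution. The fly profile was compared by Spearman rho across the 128 fly miRNAs with a mean of 10 or more counts in untreated 1:1 libraries, against the untreated 1:1 libraries of the other sets. Genes are not independent replicates, so rho carries no p.

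Single miRNAs were tested with edgeR 4.0.16 in R 4.3.3 on rounded counts: quasi-likelihood fits over all 36 libraries with 1 mean per group, entries kept by filterByExpr (minimum count 10, minimum total 15), and Benjamini-Hochberg adjustment over all tested entries of both species, called at an adjusted p below 0.05. Libraries were scaled to their mouse miRNA totals times TMM factors from mouse entries, so a change of a fly miRNA is relative to mouse miRNAs. Contrasts were each ratio, the mean of the 6 differences (the average contrast), and the linear trend over untreated groups on the log10 fly share of RNA. An entry with no read in both groups of a ratio has no finite estimate there and could not be called in the average contrast. Fixed lists of miRNAs were tested with camera in limma 3.58.1 against the other tested miRNAs of their species, with a preset correlation of 0.01 and with an estimated correlation. Ratios and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

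Named miRNAs followed a rule: the 12 most abundant tested fly miRNAs in untreated 1:1 libraries; the 4 with the largest and the 4 with the smallest change at 1:1 among those with a mean of 50 or more counts; the 8 mouse miRNAs with the largest rise and the 4 with the largest fall in the average contrast among those called and moving that way in at least 15 of 18 pairs; the 2 most abundant tested members of each list; and the 4 mouse miRNAs rising most with the fly share among those called. Only 5 mouse miRNAs met the condition for a rise. Any other name was chosen after its values were seen. Groups, tests, lists and this rule were fixed before the data were examined, as were the alternatives: TMM over both species, total counts, size factors of DESeq2 1.42.0, DESeq2 as the test, no filter, a fold of 1.5 tested with glmTreat, blocks for the replicate set or the mixture, other inputs to the ratio, other detection minimums, and leaving out replicates. The alternatives chosen after the data were seen were to count mmu-mir-184-3p as fly, to average the 4 ratios from 1:1 to 1:1000 alone, to scale by summed mouse counts without conserved miRNAs, and to leave out untreated 1:100000 or untreated 1:10000 replicate 1.

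The tests were checked on simulated counts with the depths of these libraries. Of 39 fly miRNAs raised at 1:1, 8 were called at a 4-fold rise, 31 at 16-fold and all 39 at 256-fold; at 1:1000, 1, 8 and 21 were called, and in the average contrast 1, 11 and 14. In the average contrast, 113 of 376 unchanged mouse miRNAs were called lower with the main scaling (median log2 change -0.82), against 2 with the scaling by summed mouse counts (-0.21). Counts of mouse miRNAs lower in the average contrast, and of those in the fixed lists, are therefore given with both scalings. Counts at single ratios, with blocks and with samples left out are not given with the scaling by summed mouse counts. In simulated untreated libraries a slope of 0.3 log2 was called in 38 of 50 raised miRNAs, with 4 of 259 unchanged entries called. All deposited libraries were used.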

Results

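The data were miRNA counts of 36 small RNA libraries from mixtures of RNA of Drosophila S2-S cells, a line of embryonic origin, and mouse ES cells, at 6 ratios of fly to mouse RNA, oxidised with periodate or left untreated, with 3 libraries per group. In the fly cells small RNAs carried a methyl group from Arabidopsis HEN1, and in the mouse cells miRNAs did not, so the series asks how far oxidation brings forward the miRNAs of a methylated minority. Total miRNA counts ran from 326776 to 16619583 in untreated libraries (median 4345832) and from 3654 to 1312983 in oxidised libraries (median 37848.5). The lowest totals were those of oxidised 1:1000, 1:10000 and 1:100000 replicate 1, with 3654, 4750 and 5534 counts. A count of 0 in a library of 3654 counts allows a share of up to 0.0821% of its counts (floor of 3 counts).

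Oxidised libraries held a larger share of fly miRNAs than untreated libraries at every ratio. Whether the fly reads at 1:10000 and 1:100000 were kept through oxidation was not tested. In untreated mixtures fly miRNAs took 40.9% ± 9.74 (SD, n = 3) of counts at 1:1, 7.71% ± 3.37 at 1:10, 0.879% ± 0.317 at 1:100, 0.175% ± 0.114 at 1:1000, 0.0233% ± 0.00916 at 1:10000 and 0.0244% ± 0.0341 at 1:100000. In untreated 1:1 libraries they were led by dme-bantam-3p, a growth-promoting miRNA. In oxidised mixtures they took 89.1% ± 1.48, 87.3% ± 0.0466, 74.7% ± 11.5, 49.4% ± 22.7, 26.1% ± 12.1 and 10.1% ± 9.14, with the rest of the counts under mouse entries. The ratio of fly to mouse counts was 12.1-fold higher after oxidation at 1:1 (log2 3.59 ± 0.58, SD, n = 3 pairs), 89.2-fold at 1:10 (6.48 ± 0.81), 371-fold at 1:100 (8.54 ± 0.26), 642-fold at 1:1000 (9.33 ± 0.56), 1467-fold at 1:10000 (10.52 ± 1.53) and 785-fold at 1:100000 (9.62 ± 3.00). Over all ratios fly counts were 258-fold higher relative to mouse counts (log2 8.01), in 18 of 18 pairs, with pairs from 3.08 to 12.26. The enrichment over all dilutions was 9.07 with mmu-mir-184-3p counted as fly, a choice made after the data were seen, and 9.16 without conserved miRNAs.

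The treatment over all ratios gave an exact permutation p of 3.125e-08, and with the pairs as blocks the difference of 8.01 had a sign-flip permutation p of 7.63e-06. Each is the smallest that its permutations allow. Both tests treat the mixtures of a replicate set as separate units, although these may share the RNA of the same cells. At each ratio the 3 oxidised libraries lay above the 3 untreated libraries with an exact two-sided p of 0.1, which is the smallest that 3 against 3 allows (0.1 also after adjustment over the 6 ratios). At 1:100000 the log2 difference was 6.36, 10.24 and 12.26 in replicates 1, 2 and 3. In untreated 1:100000 replicates 2 and 3, 40.6% and 28.7% of fly counts were of dme-mir-124-3p, which did not dilute with the fly RNA. The differences at 1:100000 include these counts. Over all omissions of a replicate or library the enrichment at 1:10000 lay between 9.91 and 11.38. The enrichment at 1:100000 was 10.87 without untreated 1:100000 replicate 1, whose fly share of 0.0638% (95% Wilson interval 0.0609% to 0.0668%) stood above the 0.0338% of untreated 1:10000 replicate 1 (0.0312% to 0.0366%), and it lay between 8.30 and 11.25 over all omissions.

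**Figure D1:**
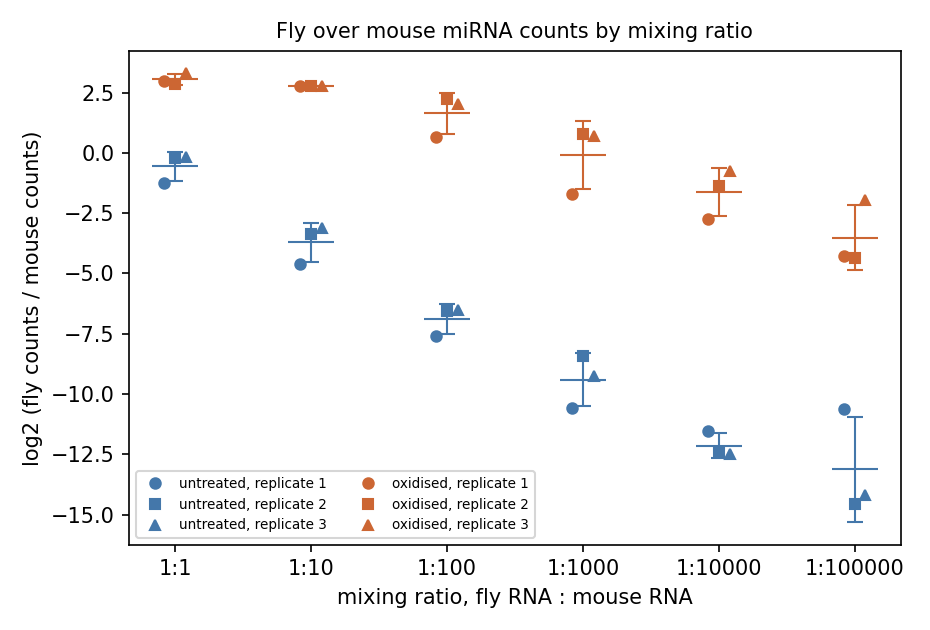
The log2 ratio of fly to mouse miRNA counts (vertical axis) is plotted against the mixing ratio of fly to mouse RNA (horizontal axis) for untreated and oxidised libraries, with a point per library, the group mean as a bar and its SD as whiskers (n = 3). Oxidised group means run from 3.05 at 1:1 to -3.51 at 1:100000 and untreated means from -0.55 to -13.13.

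The entry mmu-mir-184-3p weighed on the enrichment at high fly shares. It made up 88.0% ± 3.31 (SD, n = 3) of all mouse counts in oxidised 1:1 libraries, 82.3% ± 7.92 at 1:10 and 42.7% ± 17.3 at 1:100, against 1.38% ± 1.46 at 1:100000. Counted as a fly miRNA, a choice made after the data were seen, it raised the log2 enrichment to 6.58 at 1:1, 9.09 at 1:10 and 9.42 at 1:100, and left 9.36 at 1:1000, 10.53 at 1:10000 and 9.44 at 1:100000.

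The enrichment of fly over mouse miRNAs differed between ratios. It increased by 1.23 log2 for each 10-fold dilution of the fly RNA (exact permutation p = 8.97e-05, 18 pairs). Within replicate sets the slope was 0.44 (exact p = 0.367), 1.45 (exact p = 0.00833) and 1.79 (exact p = 0.00278) for sets 1, 2 and 3. With mmu-mir-184-3p as a fly miRNA the slope was 0.53 (exact p = 0.0192), and within sets it was -0.24 (exact p = 0.422), 0.72 (exact p = 0.0583) and 1.11 (exact p = 0.00278). The rise was then not steady: the mean enrichment was 6.58 at 1:1 and between 9.09 and 10.53 at the other ratios. At 1:100000 it was 6.33, 9.92 and 12.06 in sets 1, 2 and 3. The relation did not pass its test in set 1, the set sequenced on the HiSeq2500.

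In untreated libraries the share of fly miRNAs followed the fly RNA put in, and in oxidised libraries it followed less steeply. The slope of the log10 fly to mouse ratio on the log10 mixing ratio was 0.780 ± 0.0487 (SE) over the 18 untreated libraries, where proportional counts would give 1, with Pearson's r of 0.970 and Spearman's rho of 0.969. In the 18 oxidised libraries it was 0.410 ± 0.0405, with r of 0.930 and rho of 0.956. Each of these coefficients had a permutation p of 1e-05, the smallest that the permutations can give, and r an adjusted p of 1e-05 over both relations. Without the 2 libraries of set 1 at the highest and lowest mixing ratios, r was 0.989 in untreated and 0.921 in oxidised libraries. The libraries of sets 2 and 3 at these ratios lay as far from the median ratio and were kept. In untreated libraries the one left out at the lowest ratio had a fly share of 0.0638%. The next higher ratio of its set had 0.0338%. The higher r in untreated libraries therefore is not a neutral check on extreme libraries. Within sets 1, 2 and 3 the slopes were 0.607, 0.866 and 0.868 in untreated libraries and 0.474, 0.429 and 0.328 in oxidised libraries. Counting mmu-mir-184-3p as a fly miRNA gave 0.616 in oxidised libraries.

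At equal depth, more fly miRNAs passed the detection minimum of 3 counts in oxidised than in untreated libraries. Thinned to 3634 counts, untreated libraries held on average 41.4 fly miRNAs at 1:1, 21.99 at 1:10, 2.24 at 1:100, 0.536 at 1:1000, 0.00288 at 1:10000 and 0.00358 at 1:100000. Oxidised libraries held 58.6, 58.1, 56.1, 45.0, 38.7 and 23.3. The gain was 17.2 ± 3.19 (SD, n = 3) at 1:1, 36.1 ± 5.88 at 1:10, 53.8 ± 1.38 at 1:100, 44.4 ± 1.47 at 1:1000, 38.7 ± 4.15 at 1:10000 and 23.3 ± 10.6 at 1:100000, each with an exact p of 0.1, the smallest possible. Without thinning, the deeper untreated libraries held more fly miRNAs at 1:1, 1:10 and 1:100 (160, 135 and 99.3 against 132, 114 and 84) and fewer at 1:1000, 1:10000 and 1:100000 (57.7, 34.3 and 27 against 68.7, 57.7 and 41). The gain at 1:1000 and beyond changed by over 1.5 times with a minimum of 10 counts, as at 1:100000, where it was 7.81.

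The order of fly miRNAs by abundance was largely kept after oxidation at the ratios from 1:1 to 1:100. Across fly miRNAs with a mean of 10 or more counts, which are not independent replicates, rho between an oxidised library and the untreated 1:1 libraries of the other sets averaged 0.933 ± 0.00755 (SD, n = 3) at 1:1, 0.919 ± 0.0125 at 1:10, 0.912 ± 0.00593 at 1:100, 0.887 ± 0.0352 at 1:1000, 0.847 ± 0.0682 at 1:10000 and 0.795 ± 0.0276 at 1:100000. Untreated libraries measured the same way gave 0.977, 0.974, 0.951, 0.836, 0.730 and 0.658. The fly composition was later fitted as a mix of the oxidised and untreated 1:1 profiles of its set. Its weight on the oxidised profile was 0.963, 0.942 and 0.983 in oxidised 1:10 libraries of sets 1, 2 and 3. At 1:10000 it was 0.439, 0.296 and 0.570, and at 1:100000 0.513, 0.254 and 0.0304. Whether rho, detection and enrichment at these dilute ratios rest on fly reads kept through oxidation was not tested.

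Single fly miRNAs rose by very different amounts when the 1:1 mixture was oxidised. The largest rise among those with 50 or more counts was that of dme-mir-308-5p, 452-fold relative to mouse miRNAs (log2 8.82 ± 1.58, SE). It was followed by dme-mir-282-3p (8.42 ± 1.74) and by dme-mir-276a-5p and dme-mir-276b-5p, which had the same counts (8.34 ± 1.23). Among the abundant miRNAs, dme-mir-2a-2-3p of the mir-2 family rose by 7.77 ± 1.60, from 3.80% ± 0.132 (SD, n = 3) to 12.3% ± 1.55 of fly counts. dme-mir-33-5p, whose host gene is the fly SREBP, rose by 7.96 ± 1.64, from 2.86% ± 0.463 to 9.33% ± 2.59. dme-bantam-3p rose least among the most abundant, by 4.00 ± 1.11 (adjusted p = 0.00492), and its share of fly counts was 42.8% ± 8.36 untreated and 10.4% ± 0.214 oxidised.

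Of the 12 most abundant fly miRNAs, all were called higher at 1:1. dme-mir-317-3p rose by 4.16 ± 0.96 (SE), with shares of 3.42% and 0.797% of fly counts. dme-mir-8-3p, the fly relative of the mir-200 family, rose by 6.91 ± 1.26, with shares of 3.38% and 5.24%. dme-mir-277-3p (7.50), dme-mir-11-3p (6.45), dme-mir-282-5p (5.99), dme-mir-34-5p (5.66), dme-mir-305-5p (5.63) and the entries dme-mir-13b-1-3p and dme-mir-13b-2-3p (both 5.45) lay between. At the low end, dme-mir-2a-1-3p rose by 3.70 ± 0.90, dme-mir-9b-5p by 3.46 ± 0.77 and dme-mir-1008-3p, a mirtron, by 2.83 ± 0.69. By its name dme-mir-2a-1-3p is a copy of dme-mir-2a-2-3p from another hairpin, and how reads were shared between these entries is not known. dme-mir-9c-3p, at 2.28 ± 0.96, did not pass the test (adjusted p = 0.110). Scaled to total counts instead of mouse counts, the changes of dme-bantam-3p, dme-mir-317-3p, dme-mir-2a-1-3p, dme-mir-9b-5p, dme-mir-1008-3p and dme-mir-9c-3p turned negative, at -0.94, -0.94, -1.32, -1.53, -2.28 and -2.54.

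**Figure D2:**
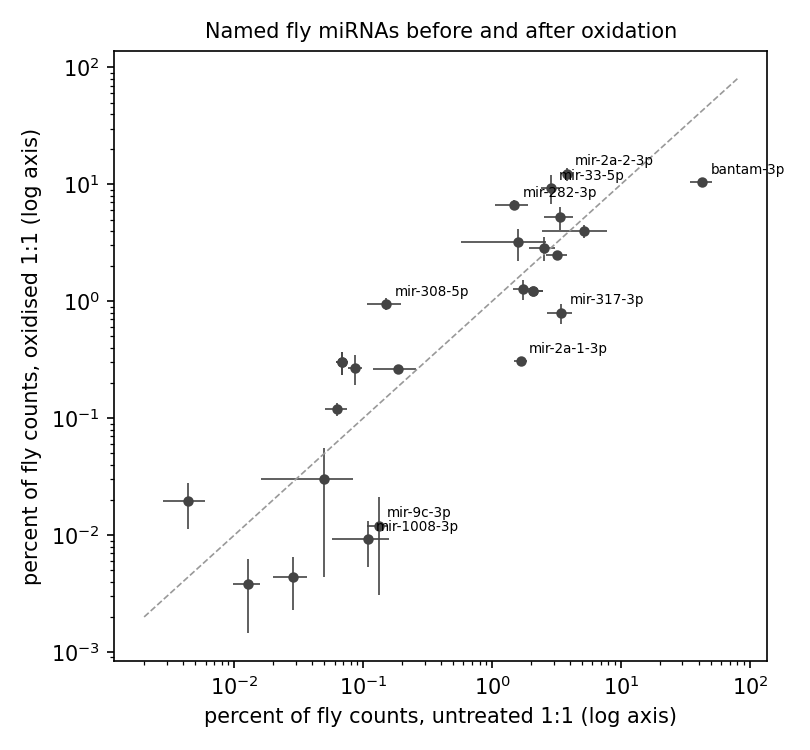
Each point is a named fly miRNA, with its percent of fly counts in untreated 1:1 libraries (horizontal log axis) and in oxidised 1:1 libraries (vertical log axis), as means with SD (n = 3), and the dashed line marks equal shares. dme-bantam-3p lies below the line, at 42.8% and 10.4%, and dme-mir-2a-2-3p above it, at 3.80% and 12.3%.

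In the test of all 117 fly miRNAs with enough counts (edgeR, relative to mouse miRNAs), 115 were higher after oxidation at 1:1, 116 at 1:10, 110 at 1:100, 96 at 1:1000, 86 at 1:10000 and 66 at 1:100000. The median log2 changes were 6.93, 9.18, 9.27, 9.31, 9.28 and 7.004. In the average over ratios 67 were higher (median 7.90): 40 others had no read in both groups of some ratio and could not be called, and of the 77 with reads at every ratio 67 were called. No fly miRNA was lower in any of these tests of edgeR, and 0 were at an unadjusted p below 0.05; DESeq2 also called 0. With the replicate set as a block, the counts were 116, 116, 110, 97, 86 and 66, and 67 in the average, which was also the count with each mixture as a block. With total counts as the scaling, 66 were higher and 4 lower at 1:1, and the median change at 1:1 moved from 6.93 to 1.86. Fitted to the 6 libraries of a ratio alone, the test called 55 at 1:1000, 43 at 1:10000 and 8 at 1:100000, and without replicate 3 it called 39 at 1:100000. DESeq2, which keeps entries with fewer counts, called more of them higher in the average, of which 82 had no oxidised count.

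In the average over ratios, where arms without reads at some ratio could not be called, no fixed list of fly miRNAs differed from the others with an estimated correlation. Of 52 tested arms of miRNAs known from S2 cells, 42 rose (42 adjusted over the list alone), with a median of 8.67 (8.90 with members at their bound) and examples in dme-bantam-3p (7.46 ± 0.53, SE) and dme-mir-2a-2-3p (9.12 ± 0.69). The list lay above the other fly miRNAs in the camera test (adjusted p = 5.3e-08), but not with an estimated correlation (adjusted p = 0.139). Of 11 arms of tissue-restricted miRNAs, 2 rose (2 adjusted over the list alone; median 6.04, or 8.59 with members at their bound), which were dme-mir-190-5p (8.21 ± 2.08) and dme-mir-278-3p (fitted 8.84 ± 0.54, with 0 untreated counts at 1:10000). This list lay below the others (adjusted p = 0.017; adjusted p = 0.139 with an estimated correlation). At 1:1, where all 52 and all 11 arms rose, both directions were the opposite: S2 arms lay below (adjusted p = 0.0112) and tissue-restricted arms above (adjusted p = 0.0398) the others, each with an adjusted p of 0.515 with an estimated correlation.

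Of 8 mirtron arms, which are miRNAs spliced from short introns, 3 rose, among them dme-mir-1003-3p (8.90 ± 0.60) and dme-mir-1006-3p (9.10 ± 0.57). Of 27 arms of fly miRNAs with mouse relatives, 16 rose, among them dme-mir-33-5p (9.13 ± 0.71) and dme-mir-34-5p (7.96 ± 0.56). Of 5 late-registered fly entries, 1 rose, which was dme-mir-2279-5p (fitted 9.99 ± 1.14, with 0 untreated counts at 1:1000, 1:10000 and 1:100000). Counts adjusted over the list alone were the same 3, 16 and 1. None of these 3 lists differed from the other fly miRNAs in the camera test of this average (adjusted p = 0.27, 0.803 and 0.0805; 0.571, 0.923 and 0.139 with an estimated correlation). Their medians were 6.54, 7.88 and 4.32, and 8.54, 8.86 and 8.42 with members at their bound. At 1:1, 7 of 8 mirtron arms, 26 of 27 arms with mouse relatives and 5 of 5 late-registered entries rose, and the late-registered entries lay above the other fly miRNAs (camera adjusted p = 0.031; adjusted p = 0.241 with an estimated correlation). S2 members took 82.5% of fly counts in untreated libraries, and tissue-restricted members 0.296%.

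Among mouse miRNAs, a small group rose with oxidation in the average over ratios, with different changes at single ratios. mmu-mir-184-3p, a miRNA conserved between insects and mammals, rose by 8.13 ± 0.50 (SE) in the average over ratios (adjusted p = 2.574e-15, higher in 18 of 18 pairs). The let-7a entries mmu-let-7a-1-5p and mmu-let-7a-2-5p, of a family that is low in ES cells, rose by 5.49 ± 0.63 and 5.47 ± 0.63 (18 of 18 pairs). For both, 701 and 1984.5 counts came from oxidised 1:1000 and 1:10000 replicate 2, and without replicate 2 mmu-let-7a-1-5p was at 3.63. mmu-mir-6236-5p rose by 4.87 ± 0.53 (18 of 18 pairs). mmu-mir-33-5p rose by 1.34 ± 0.39 (16 of 18 pairs), but was at -0.54 when scaled to total counts and at 1.17 and 1.26, no longer called, without replicate 2 or 3. From 1:1 to 1:100000 its changes were 4.10, 2.76, 0.81, 1.16, -0.42 and -0.39. By contrast, mmu-let-7a-1-5p was at 3.00 at 1:1 and not called (edgeR adjusted p = 0.301), and at 7.66 at 1:1000.

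At 1:1, where fly RNA was most abundant, 6 of 43 tested arms of mouse miRNAs with fly relatives rose, more than other mouse miRNAs (camera adjusted p = 3.51e-06; adjusted p = 0.00648 with an estimated correlation). Among them, mmu-mir-184-3p rose by 6.11 ± 1.11 and mmu-mir-33-5p by 4.10 ± 1.01. Named after their values were seen, mmu-mir-7a-1-5p and mmu-mir-7a-2-5p rose by 3.64 ± 0.48 and 3.69 ± 0.47, and mmu-mir-125b-1-5p and mmu-mir-125b-2-5p by 2.63 ± 0.89 and 2.64 ± 0.89. The list's median was -0.43 at 1:1, opposite in sign to its test (0.94 with members at their bound).

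The miRNAs of the mir-290 cluster, the main miRNA cluster of ES cells, were mostly called lower after oxidation with the main scaling. In the average over ratios 10 of 14 arms fell (13 adjusted over the list alone; median -0.63, or -0.61 with members at their bound), among them mmu-mir-294-3p (-0.88 ± 0.29) and mmu-mir-295-3p (-0.70 ± 0.20). The camera test pointed down (adjusted p = 2.25e-06; adjusted p = 0.0339 with an estimated correlation), while the list's median lay above the -0.88 of all mouse miRNAs, so the cluster is not shown to fall more than the rest. The calls were not kept: 0 of 14 arms were lower with DESeq2 size factors (median -0.20; camera adjusted p = 0.236) or summed mouse counts (median -0.05; 0.866). At 1:1, 0 of 14 arms were called (edgeR; median -0.58; camera adjusted p = 2.2e-05; adjusted p = 0.0397 with an estimated correlation). Without untreated 1:10000 replicate 1, in which mmu-mir-294-3p took 39.8% of mouse counts, its change was -0.54 and not called.

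The largest called falls were those of miRNAs with few counts. mmu-mir-138-2-5p had 2310 counts in untreated and 0 in oxidised libraries. With a floor of 3 counts over the group the fall is at least 3.05-fold relative to mouse totals with TMM factors and 2.17-fold relative to summed mouse counts without conserved miRNAs, and without replicate 2 of 1.37-fold and 0.989-fold, so a fall is not shown on every basis. mmu-mir-148b-5p had 1396 and 0 counts, with limits of 1.84-fold and 1.31-fold, and of 0.808-fold and 0.585-fold without replicate 2. It was not called with summed mouse counts and was at 1.03 in the DESeq2 fit. mmu-mir-138-1-5p had 3031 and 3 counts and mmu-mir-409-5p 3851 and 2. Without replicate 1 the calls of mmu-mir-138-2-5p, mmu-mir-138-1-5p and mmu-mir-409-5p were lost, as was that of mmu-mir-138-2-5p over the 4 ratios from 1:1 to 1:1000.

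Of 459 tested mouse miRNAs, 3.05% were higher (14) and 29.8% lower in the average over ratios (edgeR), and the median of all mouse miRNAs was -0.88. That median was -1.75 with TMM over both species, -2.84 with total counts, -0.47 with DESeq2 size factors and -0.29 with summed mouse counts, and the numbers of mouse miRNAs higher and of mouse miRNAs lower after oxidation, average over dilutions, moved to 10 and 378, 6 and 440, 14 and 38, and 16 and 24. From 1:1 to 1:100000, single ratios gave 8, 11, 13, 14, 17 and 11 mouse miRNAs higher and 0, 1, 2, 17, 98 and 10 lower (3, 13, 20, 48, 30.9% of all tested and 24 lower at an unadjusted p below 0.05; DESeq2, with its own filtering, gave 2, 2, 2, 3, 34 and 0 lower and 65, 131, 209, 32, 27 and 17 higher). At 1:10000, with the most lower calls, untreated replicate 1 had a TMM factor of 0.426, and without this library 144 were lower in the average. On simulated counts at these depths, 30.1% of unchanged mouse miRNAs were called lower in the average with the main scaling. With the replicate set as a block, 14 were higher and 153 lower, and with each mixture as a block, 13 and 107. Without replicate 1, 7 were higher and 53 lower, and without replicate 2, 11 and 76. Over the 4 ratios from 1:1 to 1:1000, 14 were higher and 43 lower. DESeq2 called 1183 higher and 23 lower, and of those higher 936 had no oxidised count.

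Other mouse lists held mostly miRNAs that were lower or not called in the average over ratios with the main scaling. In the mir-17-92 cluster and its paralogs, growth-promoting miRNAs, 15 of 30 arms fell (18 adjusted over the list alone). mmu-mir-92a-1-3p fell by 0.73 ± 0.16, while mmu-mir-19b-1-3p (-0.26 ± 0.19) and mmu-mir-19b-2-3p (-0.26 ± 0.19) were not called. The list's test was lost with an estimated correlation (camera adjusted p = 0.0146, down, then adjusted p = 0.319; median -0.80, above that of all mouse miRNAs, or -0.41 with members at their bound). In the imprinted Dlk1-Dio3 cluster 27 of 61 arms fell (31 adjusted over the list alone; camera adjusted p = 0.038, then adjusted p = 0.319 with an estimated correlation; median -1.24, or -0.52 with members at their bound), among them mmu-mir-127-3p (-0.95 ± 0.26). With summed mouse counts, these counts were 1 of 30 and 7 of 61.

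Of 51 arms of the Sfmbt2 cluster, 3 fell (0 adjusted over the list alone), including mmu-mir-467e-5p, and 0 with summed mouse counts. The fitted -2.65 ± 0.82 of mmu-mir-467e-5p rests in large part on a fit of -11.42 at 1:1000 with 0 oxidised counts, where the floor gives -1.15. Its fits at 1:1, 1:10 and 1:100 were -0.02, -0.01 and -0.59. At 1:10000 and 1:100000 they were -2.19 and -1.65, with 2 oxidised counts at each. The cluster's camera test pointed up (adjusted p = 0.005, and adjusted p = 0.509 with an estimated correlation), opposite to its median of -1.45, which was 0.02 with members at their bound. The mir-302 cluster had 1 of 5 arms lower (0 adjusted over the list alone; camera adjusted p = 0.517), and the mir-200 and mir-183 clusters, abundant in ES cells, 3 of 12 (2 adjusted over the list alone; camera adjusted p = 0.149), including mmu-mir-96-5p (-0.69 ± 0.23). With summed mouse counts both had 0 lower, and the median of the mir-302 cluster moved from -0.47 to 0.03.

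Markers of other cell types, such as blood, muscle and neurons, had 7 of 15 arms lower (7 adjusted over the list alone; camera adjusted p = 0.0504), among them mmu-mir-124-1-3p (-1.15 ± 0.23), and 2 of 15 with summed mouse counts. They made up 1.71% of mouse counts in untreated libraries, led by mmu-mir-142a-3p, while the mir-290 cluster made up 72.1%. Of 10 let-7 arms 3 rose and 1 fell (3 and 1 adjusted over the list alone). The family lay above other mouse miRNAs (camera adjusted p = 0.00148; adjusted p = 0.138 with an estimated correlation), with a median of -0.37 (-0.06 with members at their bound) against -0.88 for all mouse miRNAs. The family's median was 0.05 with DESeq2 size factors and 0.08 with summed mouse counts, and with each of these scalings 3 arms rose and 0 fell. Of 14 late-registered mouse entries 4 rose and 3 fell (the same adjusted over the list alone; camera adjusted p = 4.3e-05, up; adjusted p = 0.103 with an estimated correlation; median -1.60, or 1.90 with members at their bound). Of 43 arms with fly relatives 6 rose and 11 fell in this average (6 and 11 adjusted over the list alone; camera adjusted p = 0.0046, up; adjusted p = 0.103 with an estimated correlation; median -1.04, or 0.23 with members at their bound). The medians of these last 2 lists lay below that of all mouse miRNAs, opposite to their tests. With summed mouse counts 8 arms with fly relatives rose and 2 fell, and with DESeq2 size factors 6 rose and 5 fell. Of the late-registered entries 4 rose and 0 fell with either scaling.

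The untreated libraries were tested for mouse miRNA entries that change with the fly RNA share. mmu-mir-184-3p rose by 2.29 ± 0.24 log2 (SE) for each 10-fold rise in the fly share (adjusted p = 9.44e-10). It took 7.66% ± 3.07 (SD, n = 3) of mouse counts at 1:1, 0.756% ± 0.336 at 1:10, 0.0858% ± 0.0292 at 1:100 and 0.00407% ± 0.00427 at 1:100000. In untreated 1:1 libraries it had a mean of 94468 counts, against 216 for dme-mir-184-3p and 0.3333 for mmu-mir-184-5p, the other arm of the mouse hairpin. Far smaller slopes passed the test for mmu-mir-196a-2-5p (0.28 ± 0.09, adjusted p = 0.0163), mmu-let-7d-5p (0.27 ± 0.09, adjusted p = 0.0219) and mmu-mir-196a-1-5p (0.26 ± 0.09, adjusted p = 0.0219). mmu-let-7d-5p did not fall steadily as the fly RNA was diluted. In set 2 it was at 45.5, 43.5 and 53.1 CPM of mouse counts at 1:1, 1:10 and 1:100. At the ratios beyond it was at 8.88, 28.4 and 23.1. In set 3 it was at 47.2, 46.7 and 45.1, then at 26.4, 29.1 and 28.0. In set 1 it was at 41.7, 40.1 and 40.4, then at 38.1, 1.67 and 20.6. Its slope is thus not shown to be a steady rise with the fly share. Such steps were not tested for the mir-196a entries.

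**Figure D3:**
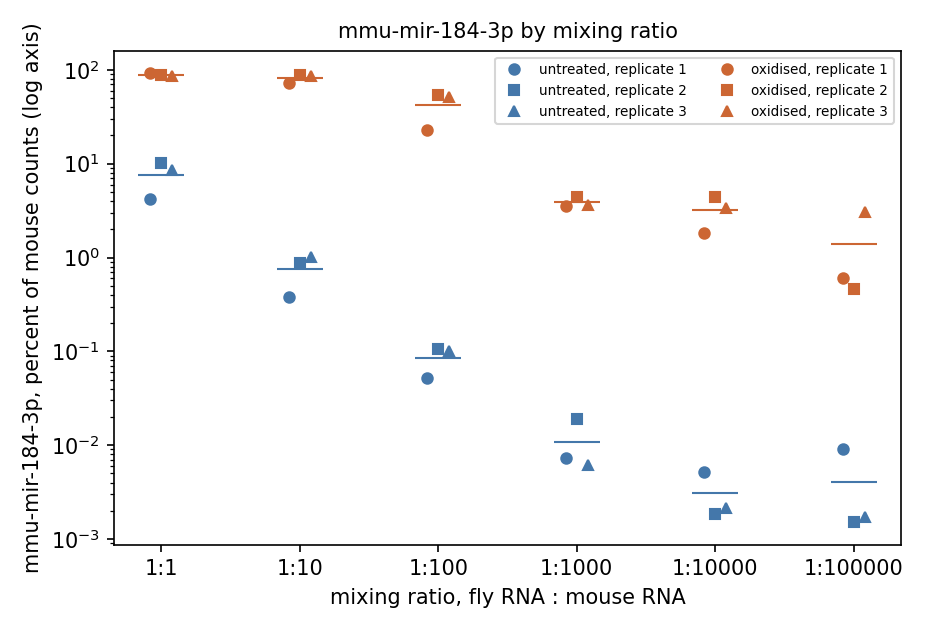
The percent of mouse miRNA counts taken by mmu-mir-184-3p (vertical log axis) is plotted against the mixing ratio of fly to mouse RNA (horizontal axis), with a point per library and the group mean as a bar (n = 3). Untreated means run from 7.66% at 1:1 to 0.00407% at 1:100000 and oxidised means from 88.0% to 1.38%.

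Of 459 mouse miRNAs, 4 rose and 9 fell with the fly share (edgeR), and with the replicate set as a block 9 rose and 12 fell. The falling miRNAs included mmu-mir-378c-5p (-0.34), mmu-mir-485-5p (-0.29), mmu-mir-300-5p (-0.28) and mmu-mir-293-5p (-0.22), named after their values were seen. The counts depended on the replicates: 57 rose and 28 fell without replicate 1, 1 and 3 without replicate 2, and 1 and 0 without replicate 3. mmu-mir-184-3p kept its call in every alternative run, while the other 3 lost theirs without replicate 2, without replicate 3, with summed mouse counts, with total counts and with TMM over both species.

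With the main scaling the let-7 family lay above other mouse miRNAs in this trend, with a median slope of 0.25 and 1 of 10 arms called (1 adjusted over the list alone; camera adjusted p = 1.99e-07; adjusted p = 0.0362 with an estimated correlation). With an estimated correlation the adjusted p was 0.397 with summed mouse counts, 0.109 with TMM over both species and 0.323 with total counts (0 of 10 arms called in each), and 0.00949 with DESeq2 size factors. In untreated 1:10000 replicate 1, mmu-let-7d-5p was at 1.67 CPM of mouse counts, against 38.1 at 1:1000 in the same set. Without this library, an alternative chosen after the data were seen, the family's median slope was 0.19 with 1 of 12 arms called (camera adjusted p = 2.69e-05; adjusted p = 0.0147 with an estimated correlation). The mir-290 cluster had a median slope of -0.04 and 1 of 14 arms called, mmu-mir-293-5p (0 adjusted over the list alone; camera adjusted p = 0.404). The Dlk1-Dio3 cluster lay below (median -0.08; camera adjusted p = 0.025) and the Sfmbt2 cluster above (median 0.09; camera adjusted p = 0.0108) the other mouse miRNAs, and neither test held with an estimated correlation (adjusted p = 0.376 and adjusted p = 0.768). With total counts the median of the Sfmbt2 cluster was -0.03.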

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

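All tests of explanations in this part were chosen after the result was seen, and the design gives no biological explanation for these patterns, so none was tested beyond the mouse cells' own miR-184.

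The enrichment of fly over mouse counts differed between mixing ratios, with a slope of 1.23 log2 for each 10-fold dilution (exact p = 8.97e-05). Fly miR-184 reads counted under the mouse entry do not account for all of it: with mmu-mir-184-3p as fly the slope was 0.53 (exact p = 0.0192), although in set 1 it was then -0.24 (exact p = 0.422). The mean enrichment was then 6.58 at 1:1 and between 9.09 and 10.53 at the other ratios, so the rest is not a steady rise. Other fly reads under mouse entries at 1:1 would have diluted the mir-290 cluster, whose share of the remaining mouse counts in oxidised libraries was at least 0.841 of that in untreated libraries. Reads carried between libraries may contribute and stay open: the fly composition of oxidised 1:100000 libraries weighed 0.513, 0.254 and 0.0304 on the oxidised 1:1 profile of their sets, against 0.963, 0.942 and 0.983 at 1:10. Loss of depth with oxidation was not tested as a cause.

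The count of mmu-mir-184-3p followed the fly RNA, at 10.5% ± 1.15 (SD, n = 3) of fly counts in untreated and 10.8% ± 1.84 in oxidised 1:1 libraries. miR-184 of the mouse cells is argued against, since its share of mouse counts would not depend on the fly input, and it was at least 471-fold higher in untreated 1:1 than 1:100000 libraries in every set. Fly miR-184 reads counted under the mouse entry may explain it: per fly count, the entry changed by -0.20 ± 0.10 log2 (SE) for each 10-fold dilution from 1:1 to 1:1000. Its ratio to fly counts was not constant elsewhere. In oxidised 1:1000 libraries it had 99, 676 and 567 counts beside 849, 26283 and 25319 fly counts in sets 1, 2 and 3. In untreated 1:100000 libraries it had 257, 51 and 147 beside 1823, 138 and 460. Fly reads alone are thus not shown to explain its counts there. No mature sequences were at hand to read the identity of both miRNAs.

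Untreated 1:100000 replicate 1 held more fly miRNA than untreated 1:10000 replicate 1, by 0.91 log2, where replicates 2 and 3 changed by -2.18 and -1.71. With more fly RNA in the mixture, its oxidised counterpart should lie at or above oxidised 1:10000, but it lay 1.53 log2 lower (-1.53). That counterpart had 275 fly counts, which weighed 0.513 on the oxidised 1:1 profile. These may include reads carried between libraries, so the comparison cannot settle this. A swap with untreated 1:1000 is argued against by that library's place 0.96 above untreated 1:10000. A swap with untreated 1:10000 replicate 1 was not tested. Fly reads from oxidised libraries of the same set are a candidate source: the fly composition weighed 0.717 (95% interval 0.665 to 0.772) on the oxidised 1:1 profile, with dme-bantam-3p at 16.1% of fly counts. In the same set untreated 1:10000 replicate 1 weighed 0.418, and untreated 1:10, 1:100 and 1:1000 replicate 1 weighed 0.0790, 0.0247 and 0.0444. In set 2 untreated 1:1000 replicate 2 weighed 0.384 and untreated 1:10000 replicate 2 0.0531. Untreated 1:10, 1:100 and 1:100000 replicate 2 weighed 0.116, 0.193 and 0.185, so such a weight alone does not show carried reads.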

How the results depend on the processing

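The alternatives chosen after the data were seen were to count mmu-mir-184-3p as fly, to average 4 ratios, to scale by summed mouse counts and to leave out untreated 1:100000 or untreated 1:10000 replicate 1. Over all alternatives, 267 values of the comparisons were the same by direction, threshold or spread and 64 moved, and the cause of a move was not tested unless stated. The enrichment over all dilutions stayed positive throughout, between 7.70 and 8.36 over omissions, 8.01 with pairs as blocks, 9.07 with mmu-mir-184-3p as fly and 9.16 without conserved miRNAs.

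Without miRNAs conserved between fly and mouse, enrichment at 1:1, enrichment at 1:10 and enrichment at 1:100 were 6.57, 8.95 and 9.21, and with mmu-mir-184-3p as fly 6.58, 9.09 and 9.42, as fewer reads then counted as mouse. Medians of log2 CPM gave 5.73 and 7.98 for enrichment at 1:1 and enrichment at 1:10, and leaving out the most abundant miRNA of each species gave 8.87 for enrichment at 1:100.

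With a minimum of 1 count, the detection gain at 1:100, detection gain at 1:1000, detection gain at 1:10000 and detection gain at 1:100000 were 62.9, 59.4, 56.4 and 41.3, and with 10 counts 37.5, 26.7, 19.8 and 7.81. Over miRNAs with a mean of 100 or more counts, the profile correlation at 1:1, oxidised, was 0.884, the profile correlation at 1:10, oxidised, 0.872, the profile correlation at 1:100, oxidised, 0.855 and the profile correlation at 1:100000, oxidised, 0.826. Without conserved miRNAs that at 1:100 was 0.922. Without a replicate the range was 0.917 to 0.944 at 1:1, 0.900 to 0.926 at 1:10 and 0.899 to 0.917 at 1:100.

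The number of mouse miRNAs lower after oxidation, average over dilutions, was 378 with TMM over both species, 440 with total counts, 38 with DESeq2 size factors, 24 with summed mouse counts, 65 with glmTreat, 43 over 4 ratios, 335 without a filter and 23 with DESeq2, and 53 to 144 without a replicate or library. Mouse miRNAs higher were 6 with total counts, 1183 with DESeq2 and 7 to 14 without a replicate or library. Mouse miRNAs rising with the fly share were 2 in a contrast of 1:1 against the rest, 1 with TMM over both species, 1 with total counts, 8 without a filter, 9 with the replicate set as a block and 1 to 57 without a replicate or library. Falling miRNAs were 0 in that contrast, 2 with TMM over both species, 21 with total counts, 1 with summed mouse counts and 0 to 28 without a replicate or library.

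The number of Drosophila miRNAs higher after oxidation at 1:1 was 66 with total counts and 231 without a filter, and of Drosophila miRNAs higher after oxidation at 1:10 it was 216 without a filter, where more entries were tested. Fits to the 6 libraries of a ratio alone, with fewer samples, gave 55 at 1:1000, 43 at 1:10000 and 8 at 1:100000, and omissions gave 39 to 69 at 1:100000. DESeq2 gave about 3.7e+02 Drosophila miRNAs higher after oxidation, average over dilutions, of which 160 had 3 or fewer oxidised counts.

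With total counts, which rise with the fly reads kept, directions turned for mmu-mir-33-5p, average over dilutions (-0.54), mmu-mir-467c-5p, average over dilutions (-1.75), dme-bantam-3p, at 1:1 (-0.94), dme-mir-1008-3p, at 1:1 (-2.28), dme-mir-2535b-3p, at 1:1 (-0.96), dme-mir-2a-1-3p, at 1:1 (-1.32), dme-mir-317-3p, at 1:1 (-0.94), dme-mir-9b-5p, at 1:1 (-1.53) and dme-mir-9c-3p, at 1:1 (-2.54). In DESeq2 they turned for mmu-mir-148b-5p, average over dilutions (1.03), mmu-mir-196a-1-5p, average over dilutions (0.22) and mmu-mir-196a-2-5p, average over dilutions (0.10). Of the other values of named fly miRNAs called at 1:1, 405 kept direction and call and 14 lost the call; for mouse miRNAs called in the average, 211 and 70, and for the trend, 28 and 23. Depth limits the oxidised libraries: at 3654 counts a miRNA under 0.0821% can go unseen.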

Other observations

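The tests of retention and of hairpin arms were chosen after the result was seen; the other splits of the samples were planned.

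The arms of a fly hairpin often differed in how far oxidation kept them. At 1:1, as a share of all fly counts, dme-bantam-5p changed by 1.09 log2 and dme-bantam-3p by -2.02, dme-mir-308-5p by 2.68 and dme-mir-308-3p by -1.47, and dme-mir-282-3p by 2.20 and dme-mir-282-5p by -0.21. The opposite order was seen in dme-mir-33-3p (0.43) and dme-mir-33-5p (1.68) and in dme-mir-9c-3p (-3.90) and dme-mir-9c-5p (0.45). Across 94 fly miRNAs, which are not independent replicates, the changes at 1:1 and at 1:10 had a rho of 0.944. Those of the 3 sets at 1:1 had rho of 0.863, 0.909 and 0.887, so the change may be a property of the entry. A property of the mature miRNA is not shown. The entries dme-mir-2a-1-3p (-2.44) and dme-mir-2a-2-3p (1.69), by name copies of the same miRNA, changed in opposite directions. By contrast, dme-mir-13b-1-3p and dme-mir-13b-2-3p both changed by -0.73. The less abundant arm may be kept more: with arms ranked in untreated 1:10 libraries, it exceeded the abundant arm by 0.861 log2 (SD 1.48) in 23 of 31 families (sign-flip permutation p = 0.00283). That test replaced a first form over hairpins, after its result was seen, which gave 0.70 in 24 of 35 hairpins (permutation p = 0.0252). Both rest on the same libraries in which the difference was noticed.

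The entry dme-mir-124-3p, of a neuronal miRNA conserved between insects and mammals, did not dilute with the fly RNA. It had 34, 1 and 3 counts in untreated 1:1 libraries and 17, 56 and 132 in untreated 1:100000 libraries of sets 1, 2 and 3. There it made up 40.6% and 28.7% of fly counts in sets 2 and 3, against 0.933% in set 1. The mouse entry mmu-mir-124-1-3p had 7560, 324 and 2790 counts in untreated 1:1 libraries and 3972, 11350 and 31655 at 1:100000. The fly entry thus moved in the direction of the mouse entry in every set, which argues against fly RNA as its source at 1:100000. Its counts are included in the fly share, enrichment and slopes. Untreated 1:10000 replicate 1 differed from other untreated libraries in mouse miRNAs, with mmu-mir-294-3p at 39.8% of mouse counts, against 24.7% or less in the other 17, and mmu-let-7d-5p at 1.67 CPM (of mouse counts). In set 3, mmu-let-7d-5p was at 47.2, 46.7 and 45.1 CPM at 1:1, 1:10 and 1:100 and at 26.4, 29.1 and 28.0 CPM at the ratios beyond.

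No other of 100 splits of the samples reached the fly count in the average over ratios, the mouse count lower or the trend counts. The fly count was nearly reached, so for it the splits do not exclude random regrouping. False calls of a scaling are not tested by these splits. The real grouping gave 67 fly miRNAs higher, against 65 in the highest other of 100 splits (as many in 1 split, the real one), and 29.8% of mouse miRNAs lower, against 10.7% at most in the larger direction of another split (as many in 1 split, the real one). On simulated counts, however, 113 unchanged mouse miRNAs were called lower with this scaling (30.1%), and with summed mouse counts 24 mouse miRNAs were lower in the data, so the 29.8% is not shown to exceed false calls. It gave 14 mouse miRNAs higher, reached by 4 of 100 splits, the real one included; the split with the most, 49, also called 65 fly miRNAs. It gave 4 mouse miRNAs rising with the fly share, against 1 at most, and 9 falling, against 3 at most, while in simulated untreated libraries 4 of 259 unchanged entries were called. For single ratios the 10 splits of 6 libraries are too few for a share under 0.05. There the real grouping gave 115, 116, 110, 96, 86 and 66 fly miRNAs, against 11, 8, 5, 39, 33 and 24 in the highest other split from 1:1 to 1:100000.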
